A study of Mus musculus with 15 samples.

How the data were processed

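RNA of the whole hippocampus of male mice was hybridised to 15 single-colour Agilent mouse arrays (Cy3). The groups were 4 dflox controls, which carry floxed alleles of both receptor genes without Cre, 4 GREmx1-cre, 4 MREmx1-cre and 3 GRMREmx1-cre mice. The glucocorticoid receptor (GR) is encoded by Nr3c1 and the mineralocorticoid receptor (MR) by Nr3c2. Each array's scanner file came from Agilent Feature Extraction 12.0, per the submitters' processing notes. Per the file headers, the processed signal of a spot is an intensity in arbitrary units that the scanner software had already corrected for background, and further columns hold flags (other values, 0 or 1) for spots well above background, saturated spots and outlier spots. The value table that the authors deposited for the whole series held the same processed intensity, equal to the scanner value at 45018 of 45018 spots on each array, so no scaling between arrays had been applied to it.

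Of the 45018 spots on an array, 43379 were not controls. Intensities were put on the log2 scale, and each array's 75th percentile over the spots that were not controls was subtracted. Spots with an outlier flag were left out (1281 over all arrays), and the remaining spots of a probe were averaged, which gave 41174 probes. Probes were named by matching their accession, without version, to a RefSeq gene table of assembly GRCm38.p6, while the design of the array was made on build mm9, so that no coordinates are given and the table served only for names and for which genes lie beside each other. Of the probes, 28223 had 1 gene symbol, 0 had several and 12951 had none and kept the name in the file. Probes well above background on at least 3 arrays were tested (30873 probes), with 1 probe per gene, the one of highest mean over all arrays. This gave 22864 genes, of which 15939 had a symbol and 6925 only an accession or probe name. A gene not well above background on any array of a group has only a bound there. Its fold is written "at least", as the brighter group's mean over the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal, on normalised log2 values.

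All 15 arrays entered 1 group means model in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, and every adjusted p is limma's, after Benjamini-Hochberg adjustment at 0.05 over the genes tested. Errors are the standard errors (SE) of the log2 fold change in that fit. The comparisons were each knockout against dflox, the knockouts against each other, and the interaction, which is the difference of GRMREmx1-cre from GREmx1-cre minus the difference of MREmx1-cre from dflox. Each genotype lay alone on 1 of 4 slides, all scanned on 1 day, so slide could not enter the model. The replicate number of an array was also its position on the slide. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

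Gene lists were written from textbook knowledge and share no tested gene: corticosteroid-induced genes, corticosteroid signalling components, activity-regulated genes, p53 and apoptosis genes, interferon-stimulated genes, complement and MHC genes, reactive astrocyte genes, activated microglia genes, glutamatergic neuron and synapse genes, and markers of dentate granule cells, immature granule neurons and progenitors, CA1, CA2 and CA3 pyramidal cells, GABAergic interneurons, astrocytes, microglia, oligodendrocytes and myelin, oligodendrocyte progenitors, endothelium, meningeal and perivascular fibroblasts, choroid plexus, thalamus and habenula, striatum and neocortex, and red blood cells. They were tested with limma's competitive test cameraPR, two-sided, with a preset correlation of 0.01 between genes, on lists with at least 3 tested genes and with adjustment over the lists of a comparison. Members past the threshold were counted over all genes and adjusted over the list alone. A further list of sex-linked genes was a check of labels only, and the 4 of its genes that were tested, all on the Y chromosome, spanned less than 1 log2 unit each over the 15 arrays.

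The genes named in the text follow a rule. Nr3c1 and Nr3c2 are always named. In each comparison with dflox, the rule takes the 10 largest rises and 10 largest falls among genes with a symbol that passed the threshold, had every knockout array on the same side of every dflox array, and were well above background on every array of the brighter group. It also takes up to 4 members of each list with the smallest adjusted p. In the other comparisons it takes 5 rises and 5 falls, for the interaction without the demand on single arrays. Genes outside it were named after their values were seen: Hif3a in GREmx1-cre, Npnt, Pdyn and Fosl2 in MREmx1-cre, Pdyn, Rasl10a, Prox1, Cebpd, Sgk1 and Pdk4 in GRMREmx1-cre, and Fosb in the interaction. Ttr, Kl and Synpo2 were named because their values on 1 array stood out. Results for some list members are not reported here.

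The model, lists, comparisons, naming rule and most alternatives were fixed before the data were examined. The alternatives were normexp background correction (offset 50) on the median signal, since the files lack the mean signal, quantile normalization, scaling to each array's median, the authors' value table, no filter, a filter on all 15 arrays, every probe on its own, only the arrays compared, eBayes with trend and robust fitting, array weights, the replicate number, which is the slide position, as a block, each array left out in turn, a fold minimum of 1.5, and camera with an estimated correlation. Further alternatives were chosen after seeing the data, namely a pair of arrays that stood apart left out together, genes beside the targeted loci left out, normexp on each array's median background, and the targeted genes left out of the list of corticosteroid signalling components. For the comparisons that share the dflox arrays, unchanged groups were simulated 20 times against the same controls, and the controls were also split 2 and 2 in each of the 6 ways.

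The scripts were tested on simulated data with 100 genes changed 2-fold and 100 changed 1.5-fold. Recovery of the 2-fold and 1.5-fold genes was 84% and 64% for GREmx1-cre vs dflox, 87% and 57% for MREmx1-cre vs dflox, 75% and 56% for GRMREmx1-cre vs dflox, 79% and 62% for GRMREmx1-cre vs GREmx1-cre, 75% and 61% for GRMREmx1-cre vs MREmx1-cre, 86% and 67% for MREmx1-cre vs GREmx1-cre, and 74% and 37% for the interaction. False calls made up between 2.35% (MREmx1-cre vs GREmx1-cre) and 7.36% (GRMREmx1-cre vs GREmx1-cre) of the calls in these simulations. The simulated noise was drawn independently for each gene and array, so these rates leave out any correlation between genes or between arrays. The number of arrays limits the precision of every value.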

Results

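Transcript levels were measured in the hippocampus of adult male mice in which the forebrain Cre line Emx1-Cre had removed GR, MR or both. The arrays covered 4 dflox control mice, 4 GREmx1-cre mice lacking GR, 4 MREmx1-cre mice lacking MR and 3 GRMREmx1-cre mice lacking both. The 75th percentile of intensity lay between 821 and 1027 on the 15 arrays, and between 28083 and 30206 probes per array were well above background. Values below are log2 fold changes ± SE relative to the reference group unless another quantity is named. Each genotype lay alone on its slide, so slide and genotype cannot be told apart in any comparison.

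Nr3c1, which encodes GR, was lower in every array of the lines that lack GR than in every other array. Its log2 level relative to the 75th percentile ran from 1.49 to 1.79 in dflox, from -0.66 to -0.53 in GREmx1-cre, from 2.08 to 2.28 in MREmx1-cre and from -0.08 to 0.09 in GRMREmx1-cre. The Nr3c1 transcript fell to 21.2% of its dflox level in GREmx1-cre (-2.24 ± 0.0776, adjusted p = 1.36e-08, n = 4 and 4) and to 32.1% in GRMREmx1-cre (-1.64 ± 0.0838, adjusted p = 7.42e-07, n = 3 and 4). It rose 1.45-fold in MREmx1-cre (adjusted p = 0.00165, n = 4 and 4), which by the design as read here carries no floxed Nr3c1 allele, unlike dflox. The other Nr3c1 probes moved the same way in these comparisons. Nr3c2, which encodes MR, rose in GREmx1-cre (0.42 ± 0.0859, adjusted p = 0.0212). By the design as read here GREmx1-cre carries no floxed Nr3c2 allele, unlike dflox, so this rise cannot be told from a difference in allele. The other Nr3c2 probes stood at 0.16 and 0.51 in GREmx1-cre (limma's unadjusted p = 0.417 and 0.0771). The call of the probe used was lost without dflox replicate 3 (log2 between 0.37 and 0.47 over the arrays left out), GREmx1-cre replicate 3 or GREmx1-cre replicate 4. In GRMREmx1-cre the Nr3c2 probe fell (-0.31 ± 0.0928, adjusted p = 0.0394). This no longer held without dflox replicate 1, 2 or 4, GREmx1-cre replicate 3, or GRMREmx1-cre replicate 2 or 3 (-0.36 to -0.21), nor with slide position as a block (-0.29), and normexp background correction turned it to 0.96. On the GRMREmx1-cre arrays that correction fitted background means far from those of the other arrays, as given below. In MREmx1-cre Nr3c2 stood at -0.11 (adjusted p = 0.48), and the lowest of the Nr3c2 probes at -0.77. The files do not say whether the Nr3c1 and Nr3c2 probes lie in the deleted exons. A probe outside the deleted part checks nothing, so the Nr3c2 values do not test whether MR was lost.

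**Figure D1:**
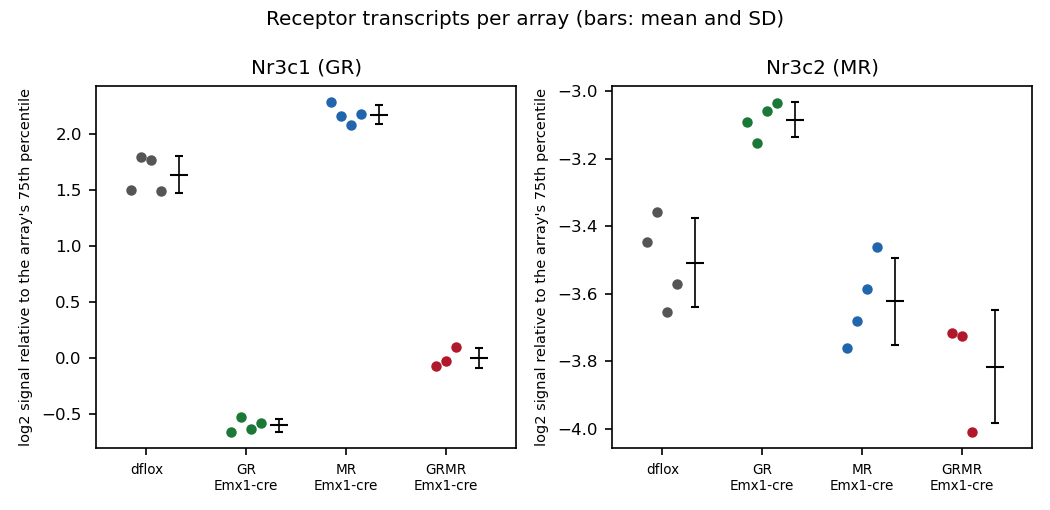
Log2 intensity of Nr3c1 and Nr3c2 relative to each array's 75th percentile (vertical axis) on every array of the 4 genotypes (horizontal axis), with points for arrays and bars for the mean and SD. Nr3c1 lies between -0.66 and 0.09 on the arrays of the lines lacking GR and between 1.49 and 2.28 on the others, while the Nr3c2 levels of all genotypes lie between -4.01 and -3.04.

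The first comparison asks which hippocampal transcripts differ after loss of GR where MR is present. By the design as read here, GREmx1-cre mice also lack the floxed Nr3c2 allele that dflox mice carry. The comparison alone cannot tell loss of GR from that difference in allele. Whether a variant linked to that allele reaches the genes of this paragraph was not tested. In GREmx1-cre, the astrocytic ethanolamine-phosphate lyase Etnppl fell to 11.5% of its dflox level (-3.12 ± 0.324, adjusted p = 0.000562, n = 4 and 4). Lipoprotein lipase, Lpl, fell 2.51-fold (-1.33 ± 0.23, adjusted p = 0.0107). The chemokine Ccl17 fell 2.49-fold (-1.32 ± 0.173, adjusted p = 0.0026) and the cytochrome P450 gene Cyp4f15 fell as well (-1.06 ± 0.147, adjusted p = 0.00345). The long non-coding RNA Crnde rose 6.08-fold (2.61 ± 0.207, adjusted p = 4.71e-05), and Tph2, the neuronal enzyme of serotonin synthesis, rose 2.03-fold (1.02 ± 0.16, adjusted p = 0.00644). With joint loss, where GR is absent too, Crnde lay below the sum of the single losses (interaction -2.76). Smaller or less certain rises were those of the taste receptor Tas2r118 (1.17), the chitinase-like gene Chil3 (1.14), the pheromone receptor Vmn1r227 (1.02), Olfr1211 (at least 1.7-fold) and the B cell receptor component Cd79a (at least 1.42-fold). Nat8f5 (-1.45) and Fam83d (-1.01) fell. Each of these last 7 calls was lost on leaving out at least 1 dflox or GREmx1-cre array, for Tas2r118 (1.08 to 1.34) and Nat8f5 (-1.70 to -1.23) dflox replicate 3 alone.

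Of the largest changes in GREmx1-cre, 6 belong to genes among the 200 tested genes nearest to Nr3c2, 100 on either side. These were the rises of the sodium iodide symporter Slc5a5 (1.59 ± 0.215, adjusted p = 0.00283), of Slc35e1 (1.06 ± 0.0844, adjusted p = 4.71e-05, with another probe at -0.39) and of the cytokine Il15 (1.74 ± 0.399, adjusted p = 0.0345, above background on 2 of 4 dflox arrays). The falls were those of Ocel1 (-2.38 ± 0.365, adjusted p = 0.0056), of Fam32a (-1.06 ± 0.079, adjusted p = 4.14e-05, with another probe at -0.03) and of the erythroid transcription factor Klf1 (-1.59, adjusted p = 0.0296). The Il15 call was lost without dflox replicate 1 or 3 or any 1 GREmx1-cre array (1.28 to 1.96). That of Klf1 was lost without dflox replicate 2 or GREmx1-cre replicate 1, 2 or 4 (-1.78 to -1.24). In all, 48 of these 200 neighbours changed (24%), 25 up and 23 down, against 2.88% of the other genes with a symbol. The design of the series, as read here, gives GREmx1-cre mice no floxed Nr3c2 allele, unlike dflox, MREmx1-cre and GRMREmx1-cre mice. The full genotype of each mouse is not given in the sources used here. Of the 48 genes, 2 were called in the same direction in GRMREmx1-cre vs dflox. In contrast, 41 were called in the opposite direction in GRMREmx1-cre vs GREmx1-cre and 42 in MREmx1-cre vs GREmx1-cre.

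**Figure D2:**
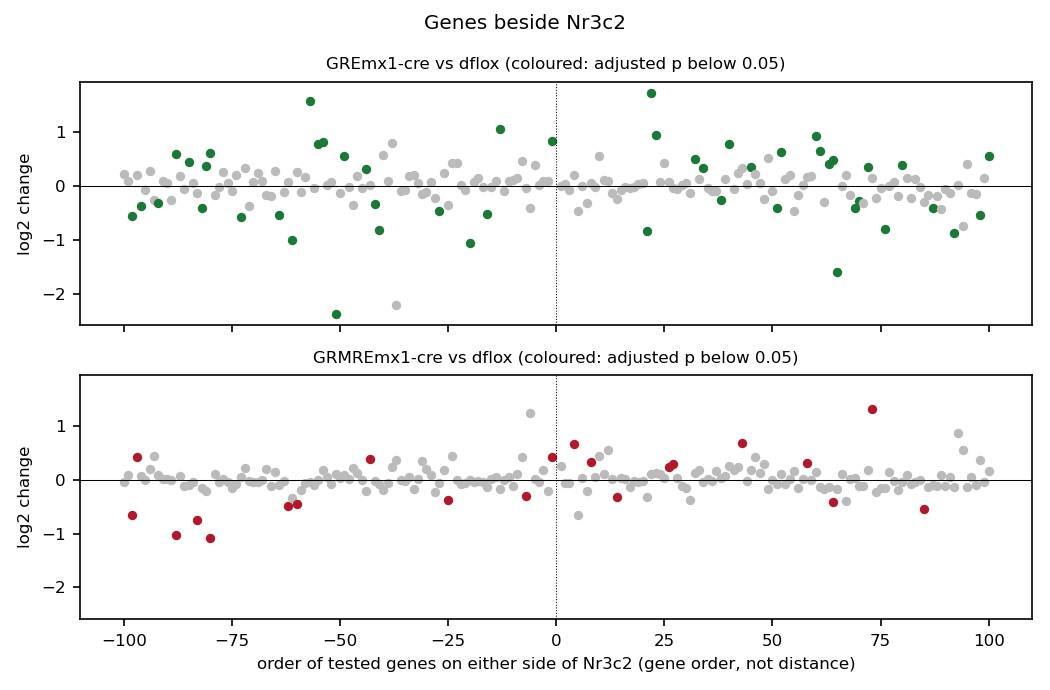
Log2 fold change (vertical axis) of the 100 tested genes on either side of Nr3c2, in their order along the chromosome (horizontal axis, gene order and not distance), in GREmx1-cre vs dflox (upper panel) and GRMREmx1-cre vs dflox (lower panel), with 1 point per gene, coloured where it passed the adjusted threshold. Coloured points number 48 in the upper panel and 21 in the lower, and the median size of the change of the 48 genes is 0.557 in the upper panel and 0.125 in the lower.

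Among the lists, the corticosteroid-induced genes were lower in GREmx1-cre (mean -0.174, camera adjusted p = 0.000818; adjusted p = 0.78 with an estimated correlation). The list had 1 riser, Hif3a (0.68), 4 fallers and 23 of 28 not past the threshold (1 rose and 9 fell adjusted over the list alone). The fallers were the kinase Sgk1 (-0.83 ± 0.179, adjusted p = 0.0261), the metallothionein Mt1 (-0.29), the kinase inhibitor Errfi1 (-0.36) and Plekhf1 (-0.85). Each of these 4 calls was lost without at least 1 array, for Sgk1 without dflox replicate 1, 2 or 3 or GREmx1-cre replicate 1, 2 or 3 (log2 up to -0.74). Activity-regulated genes were lower as a list (mean -0.373, camera adjusted p = 1.36e-07; adjusted p = 0.78 with an estimated correlation), although 0 of 22 members passed limma's threshold over all genes or adjusted over the list alone (10 at an unadjusted p below 0.05). Their mean relative to all arrays was -0.188 on dflox replicate 1 and between 0.267 and 0.463 on the other dflox arrays. The meningeal and perivascular fibroblast markers were also lower (mean -0.307, camera adjusted p = 0.00215; adjusted p = 0.78 with an estimated correlation). Of 10 tested, the collagens Col3a1 (-0.86 ± 0.145) and Col1a2 (-0.54) fell, and 3 members fell adjusted over the list alone. The Col1a2 call was lost without dflox replicate 1 or 3 or GREmx1-cre replicate 4 (-0.61 to -0.44). The fibroblast mean relative to all arrays was -0.458 on GREmx1-cre replicate 1 and 0.0335 to 0.115 on the other GREmx1-cre arrays. That array also had the highest thalamus and habenula mean (0.435, against -0.2 to -0.191), with Synpo2 at a log2 level of 1.82 against -5.39 to -4.77. The other 22 lists were not called (adjusted p from 0.0986 to 0.986), though the endothelial markers were without GREmx1-cre replicate 3 (adjusted p = 0.0245). Mean, median and test differed in sign for the CA3, astrocyte, activated microglia and complement lists. Of 19 microglia markers, 1 rose and 1 fell (5 and 3 adjusted over the list alone), the faller being the receptor Gpr34 (-0.31 ± 0.0551, adjusted p = 0.0122). In the reactive astrocyte list S100a10 rose 1.59-fold (0.67 ± 0.0831, adjusted p = 0.00194).

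In total 721 of 22864 genes changed in GREmx1-cre vs dflox, 518 up and 203 down, and 236 of them by at least 1.5-fold. The count fell to 268 without dflox replicate 3, to 324, 334 and 465 without GREmx1-cre replicate 4, 3 and 1, and to 469 without dflox replicate 1. The share of rises of 71.84% dropped to 57.65% with quantile normalization (245 up, 180 down) and to 56.14% with median scaling (247 up, 193 down). Of the called genes with several probes, 37 of 164 had probes that differed in sign. In MREmx1-cre and GRMREmx1-cre vs dflox these were 41 of 429 and 123 of 889. They were 159 of 1064 for GRMREmx1-cre vs GREmx1-cre and 20 of 98 for GRMREmx1-cre vs MREmx1-cre. For MREmx1-cre vs GREmx1-cre and the interaction they were 101 of 701 and 8 of 51.

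The second comparison asks what depends on MR where GR is present. In MREmx1-cre, the desmosomal gene Dsp, a dentate marker, fell 5.57-fold (-2.48 ± 0.133, adjusted p = 3.14e-06, n = 4 and 4), the calcium-binding protein gene Calb1 fell 2.62-fold (-1.39 ± 0.109, adjusted p = 3.94e-05) and the CA1 marker Spink8 fell 4.57-fold (-2.19 ± 0.259, adjusted p = 0.00052). The CA1 marker Wfs1 rose (0.58 to 0.72 with each array left out), and the CA1 list had 1 riser and 2 fallers of 12. The retinoic acid synthesis enzyme Aldh1a3 rose 7.36-fold (2.88 ± 0.231, adjusted p = 3.94e-05). Fkbp5, a co-chaperone of GR that corticosteroids induce, fell 2.8-fold (SE 0.21, adjusted p = 0.00144). Further falls were those of the BMP antagonist Grem1 (-2.59 ± 0.321), Olfml2b (-2.37 ± 0.203), the serine protease Tmprss6 (4.72-fold), Fam160a1 (3.52-fold), Strip2 (3.43-fold), the mast cell protease Mcpt4 (-1.69), Fyb2 (-1.68) and Tmem215 (at least 1.99-fold). Rises were those of the keratins Krt12 (3.98-fold) and Krt10 (3.66-fold), the small heat shock protein Hspb3 (3.12-fold), the transcription cofactor Dach1 (2.77-fold), Stpg1 (2.69-fold), the aldolase Dera (2.64-fold), Bmp3 (2.46-fold), the cytochrome P450 gene Cyp2c23 (at least 1.64-fold) and the kallikrein Klk1 (at least 1.32-fold).

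Corticosteroid-induced genes fell as a list in MREmx1-cre (mean -0.37, camera adjusted p = 1.91e-11; adjusted p = 0.0351 with an estimated correlation). It had 0 risers and 8 fallers of 28 (13 adjusted over the list alone). Among them were Errfi1 (-0.73, adjusted p = 0.000251), the transcription factor Cebpd (-0.91, adjusted p = 0.0093) and Tsc22d3, the glucocorticoid-induced leucine zipper (-0.49, adjusted p = 0.0096). The dentate granule cell markers were lower (mean -0.402, camera adjusted p = 1.74e-06; adjusted p = 0.293 with an estimated correlation). Of 19 members 8 fell, among them Npnt (-1.10), while Rasl10a (0.57) and the opioid precursor Pdyn (0.78) rose (9 and 2 adjusted over the list alone). CA2 pyramidal markers fell (mean -0.353, camera adjusted p = 1.74e-06; adjusted p = 0.00967 with an estimated correlation). Amigo2 (-1.31, adjusted p = 0.00175), Necab2 (2-fold) and Vit (-0.80) were among 6 fallers of 16 (9 adjusted over the list alone). CA3 pyramidal markers fell too (mean -0.315, camera adjusted p = 9.34e-06; adjusted p = 0.0289 with an estimated correlation). Homer3 (-0.91) and Grik4 (-0.41) were the 2 fallers of 9 (6 adjusted over the list alone). The glutamatergic genes were lower (mean -0.126, camera adjusted p = 0.00103), with falls of Nptx1 and Snap25 among 17. Activity-regulated genes were lower too (mean -0.362, camera adjusted p = 2.63e-06), with falls of Gadd45b (-0.68), Egr4 (-0.63), Arc (-0.93), Fosb (-0.71) and Fosl2 (-0.57) among 22. So were the fibroblast markers (mean -0.367, camera adjusted p = 0.000138), with falls of Ogn (2-fold) and Col1a2 among 10. With an estimated correlation the glutamatergic, activity-regulated and fibroblast lists were not called (adjusted p = 0.322, 0.293 and 0.322). Adjusted over the list alone, 1 of the glutamatergic genes rose and 2 fell, 6 activity-regulated genes fell, and 3 fibroblast markers fell.

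Microglia markers were higher in MREmx1-cre (mean 0.269, camera adjusted p = 5.21e-08; adjusted p = 0.109 with an estimated correlation). They had 7 risers and 0 fallers of 19 (13 adjusted over the list alone). Among the risers were Fcrls (0.59), Gpr34 (0.32) and the complement gene C1qc (0.30, lost without MREmx1-cre replicate 2, range 0.25 to 0.35). Choroid plexus markers were lower (mean -1.13, camera adjusted p = 0.00226; adjusted p = 0.715 with an estimated correlation), although 0 of 13 passed limma's threshold, adjusted over the list alone too (0 at an unadjusted p below 0.05). That mean came from MREmx1-cre replicate 2, whose choroid mean relative to all arrays was -4.14 against 0.089 to 1.04 on the other MREmx1-cre arrays. Without it the list mean was 0.023 (adjusted p = 0.665). On that array the log2 levels of Ttr, which encodes transthyretin, and Kl, which encodes klotho, were -2.58 and -2.44 against 3.94 to 4.77 and 1.24 to 1.92. The other 16 lists were not called (adjusted p from 0.0748 to 0.912). Interferon-stimulated genes were called without MREmx1-cre replicate 2 (adjusted p = 0.0159), oligodendrocyte progenitor markers without dflox replicate 2 (0.0386) or MREmx1-cre replicate 4 (0.0164). Red blood cell genes were called without dflox replicate 3 (0.0302), MREmx1-cre replicate 1 (0.0254) or GRMREmx1-cre replicate 3 (0.0451). Signs of mean, median and test differed for the immature granule neuron, CA1, GABAergic, reactive astrocyte, p53 and thalamus lists.

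Altogether 1557 genes changed in MREmx1-cre vs dflox, 962 up and 595 down, and 429 by at least 1.5-fold. The count was 1013 without dflox replicate 1 and also without MREmx1-cre replicate 4, and the share of rises of 61.79% dropped to 50.92% with median scaling (524 up, 505 down). The calls of Arc, Fosb, Nptx1, Snap25 and Col1a2 were each lost without at least 1 array, for Arc without dflox replicate 2, 3 or 4 or MREmx1-cre replicate 2, 3 or 4 (-1.19 to -0.74).

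**Figure D3:**
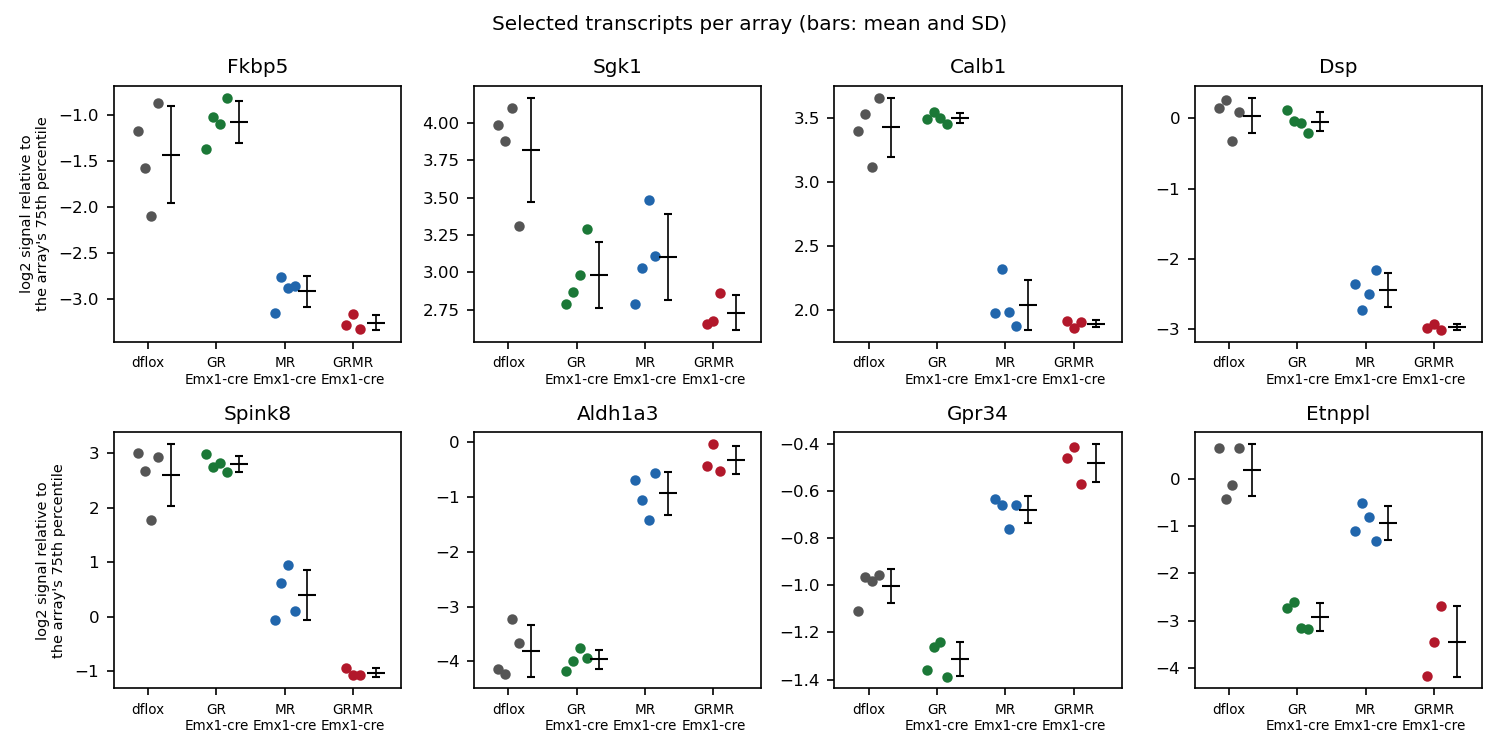
Log2 intensity relative to each array's 75th percentile (vertical axis) of Fkbp5, Sgk1, Calb1, Dsp, Spink8, Aldh1a3, Gpr34 and Etnppl on every array of the 4 genotypes (horizontal axis), with points for arrays and bars for the group mean and SD. Group means of Aldh1a3 are -3.81 in dflox, -3.96 in GREmx1-cre, -0.93 in MREmx1-cre and -0.33 in GRMREmx1-cre, while those of Etnppl are 0.19, -2.92, -0.94 and -3.44.

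Joint loss of GR and MR went with the most changes, and by the design as read here these mice differ from dflox by Cre alone, though full genotypes are not given. In GRMREmx1-cre, Etnppl fell 12.4-fold to 8.05% of its dflox level (SE 0.35, adjusted p = 7.36e-05, n = 3 and 4) and Spink8 fell 12.2-fold (-3.61 ± 0.279, adjusted p = 1.35e-05). Dsp fell 8.09-fold (-3.02 ± 0.144, adjusted p = 7.2e-07), as did Rasd1, a Ras-like gene induced by dexamethasone (-3.00 ± 0.22, adjusted p = 9.74e-06). Aldh1a3 rose 11.2-fold (3.48 ± 0.25, adjusted p = 9.43e-06) and the chemokine Cxcl5 rose 5.98-fold (2.58 ± 0.423, adjusted p = 0.00149). Other large falls were those of Grem1 (at least 8.76-fold), Olfml2b (6.37-fold), Tmprss6 (5.45-fold), Wipf3 (4.48-fold), the TGF-beta family member Lefty1 (4.08-fold) and Tmem215 (at least 1.8-fold). Other rises were those of Gpr142 (3.45 ± 0.651, above background on 1 of 4 dflox arrays), Otoa (at least 3.68-fold), C1qtnf3 (at least 3.14-fold), the olfactory receptors Olfr594 (at least 3.19-fold), Olfr979 (at least 2.46-fold) and Olfr295 (at least 1.38-fold), Cyp2c23 (at least 2.19-fold) and Pdcl2 (at least 1.83-fold). The call of C1qtnf3 was lost without dflox replicate 2 or GRMREmx1-cre replicate 2 (2.04 to 3.02), and that of Pdcl2 without GRMREmx1-cre replicate 1 or 2 (2.25 to 2.64). That of Otoa held, but its fitted value of 2.95 fell to 1.88 without GRMREmx1-cre replicate 1, so the bound above is lower without that array. With normexp background correction the falls of Grem1 (0.49), Tmem215 (1.33) and Tmprss6 (0.61) turned into values above 0. On the GRMREmx1-cre arrays that correction fitted background means of -30.6, -804.5 and -107, against -0.331 to 2.42 on the others. With normexp on each array's median background no sign reversed. The reversals under planned normexp given above and below therefore rest on that fit.

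Corticosteroid-induced genes fell as a list in GRMREmx1-cre (mean -0.459, camera adjusted p = 7.71e-10; adjusted p = 0.0767 with an estimated correlation). It had 18 fallers and 1 riser of 28 (19 and 3 adjusted over the list alone). Fkbp5 fell 3.55-fold (-1.83 ± 0.227, adjusted p = 0.000269), Cebpd by 1.25, Sgk1 by 1.09 and the transcriptional repressor Bcl6 by 0.98 on the log2 scale. The riser was Pdk4, a kinase that restrains glucose oxidation (0.56). Dentate granule cell markers fell (mean -0.582, camera adjusted p = 4.73e-08; adjusted p = 0.15 with an estimated correlation). They had 12 fallers and 2 risers of 19 (the same numbers adjusted over the list alone). Calb1 (-1.53, adjusted p = 1.35e-05) and Npnt (-1.68, but 0.91 with normexp background correction) fell, and Pdyn (1.23) and Rasl10a (0.41) rose. Prox1, the transcription factor that defines granule cells, stood at 0.0047 (adjusted p = 0.989). The CA2 markers (mean -0.199, camera adjusted p = 0.000777), CA3 markers (mean -0.317, camera adjusted p = 0.000777) and glutamatergic genes (mean -0.227, camera adjusted p = 2.12e-05) were lower too. Their values were adjusted p = 0.0767, 0.0767 and 0.15 with an estimated correlation. Of these, 7 of 16 CA2 markers fell, among them Amigo2 (-1.19, but 0.0044 with normexp background correction) and Necab2 (-1.02). Further, 4 of 9 CA3 markers fell, with Homer3 at -1.02, and 6 of 17 glutamatergic genes fell, with Nptx1 at -0.72. None of the 3 lists had a riser over all genes, and adjusted over the list alone 1 rose and 8 fell, 4 fell, and 7 fell.

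Microglia markers rose in GRMREmx1-cre (mean 0.387, camera adjusted p = 3.88e-09; adjusted p = 0.0767 with an estimated correlation), with 13 risers and 0 fallers of 19 (17 adjusted over the list alone). Among the risers were Gpr34 (0.52, adjusted p = 0.000177), the receptor Trem2 (0.51, adjusted p = 0.000655) and C1qc (0.50, adjusted p = 0.000795). The activated microglia genes were higher as well (mean 0.385, camera adjusted p = 0.0359; adjusted p = 0.607 with an estimated correlation). There were rises of the integrin Itgax (2.17), the chemokine Ccl4 (1.21), the lysosomal gene Cd68 (0.52) and the cystatin Cst7 (at least 4.47-fold) among 5 risers of 23 (7 adjusted over the list alone). That list call was lost without dflox replicate 4 (adjusted p = 0.0925), GREmx1-cre replicate 1 (0.0681) or GRMREmx1-cre replicate 2 (0.127), with slide position as a block (0.0711), and under normexp background correction, where the test turned downward. The fibroblast markers were lower (mean -0.305, camera adjusted p = 0.0323; adjusted p = 0.607 with an estimated correlation). They had 2 fallers of 10, Ogn (-0.90) and Col1a2 (-0.38), the same number adjusted over the list alone. The Col1a2 call was lost on leaving out any 1 of 11 of the 15 arrays (-0.44 to -0.33). The list call was lost without dflox replicate 1 (adjusted p = 0.066), dflox replicate 3 (0.0853) or GRMREmx1-cre replicate 1 (0.053), and with quantile normalization or median scaling.

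The other 17 lists were not called in GRMREmx1-cre, and camera's adjusted p stands in parentheses after each mean. Corticosteroid signalling components had a mean of -0.168 (adjusted p = 0.0526, and called without dflox replicate 1 at 0.0434, dflox replicate 3 at 0.0276, MREmx1-cre replicate 2 at 0.0496 or GRMREmx1-cre replicate 1 at 0.0473). That list holds Nr3c1 and Nr3c2 themselves, and without them its mean was -0.0341 (0.384). Immature granule neuron and progenitor markers had a mean of 0.12 (adjusted p = 0.244), with 5 risers and 0 fallers of 15, among them the neurogenic factor Sox11 (0.49). Means were -0.331 for CA1 markers (0.377), 0.0064 for GABAergic interneuron markers (0.498) and -0.0579 for activity-regulated genes (0.315, and 0.00476 without dflox replicate 1). The CA1 markers had 2 risers, among them Wfs1, and 3 fallers of 12. Astrocyte markers had a mean of 0.0611 (0.498), with a rise of the water channel Aqp4 (1.69-fold) and a fall of Aldoc (-0.54). Reactive astrocyte genes had a mean of 0.147 (0.303), with 8 risers, among them S100a10 (1.06, adjusted p = 3.08e-05), and 2 fallers, among them Ptgs2 (-1.03, but 0.26 with normexp background correction). For interferon-stimulated genes, complement and MHC genes, and p53 and apoptosis genes the means were 0.143 (0.384), 0.0523 (0.605) and 0.117 (0.675). Oligodendrocyte and myelin markers, oligodendrocyte progenitor markers and endothelial markers had means of -0.0345 (0.371), 0.167 (0.157) and 0.104 (0.384). Choroid plexus markers (-0.626, adjusted p = 0.143), thalamus and habenula markers (0.0024, 0.498), striatum and neocortex markers (0.129, 0.384) and red blood cell genes (-0.332, 0.244) complete the lists. The choroid plexus markers were called without MREmx1-cre replicate 2 (0.00287). Signs of mean, median and test differed for the CA1, GABAergic, p53 and thalamus lists.

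**Figure D4:**
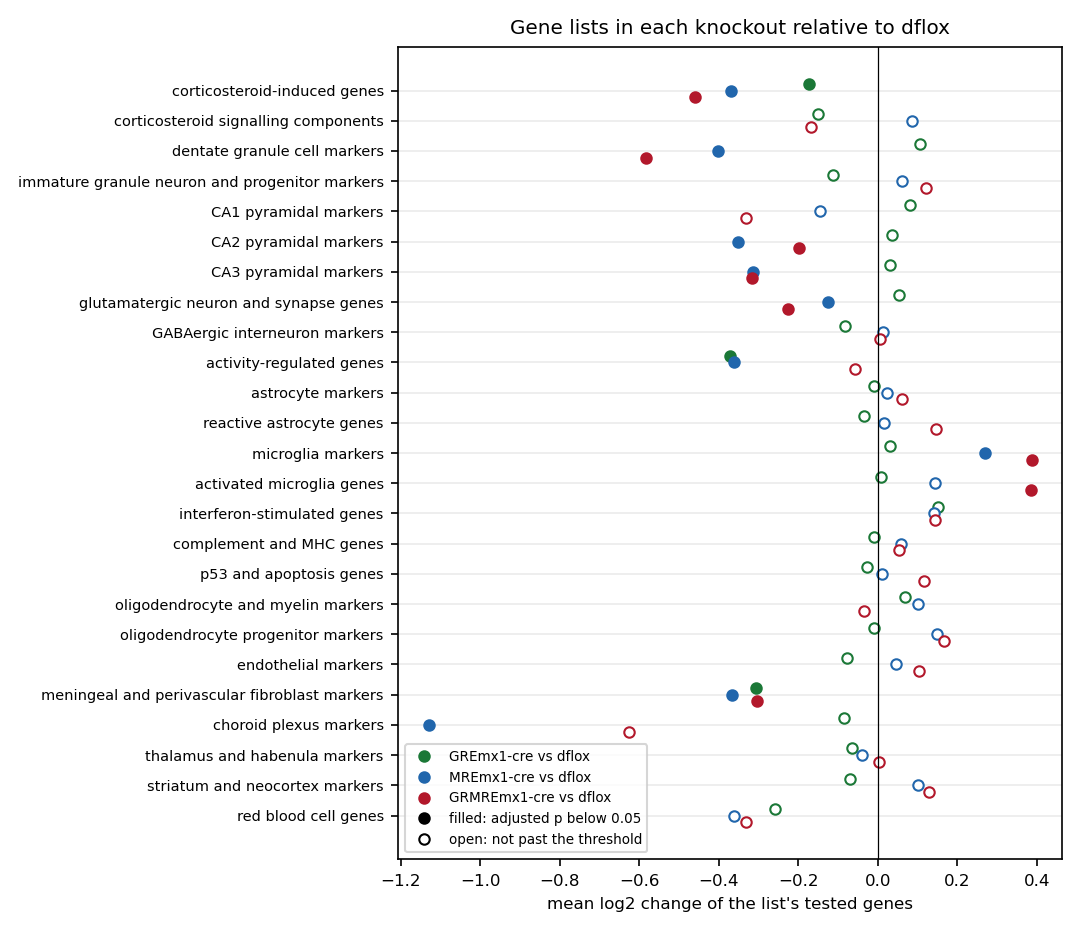
Mean log2 fold change of each gene list (horizontal axis, lists on the vertical axis) in the 3 comparisons with dflox, shown by colour, with filled points where camera's adjusted p passed the threshold and open points elsewhere. Corticosteroid-induced genes lie at -0.174, -0.37 and -0.459 in GREmx1-cre, MREmx1-cre and GRMREmx1-cre, and microglia markers at 0.0315, 0.269 and 0.387.

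A total of 3716 genes changed in GRMREmx1-cre vs dflox, 2610 up and 1106 down, and 1435 by at least 1.5-fold. The count was 2265 without GRMREmx1-cre replicate 2, and the share of rises of 70.24% dropped to 47.34% with median scaling (1539 up, 1712 down). Of the genes divided by mean signal into 5 equal parts, 643 rose and 63 fell in the dimmest part, and 258 rose and 379 fell in the brightest. Of 300 olfactory receptor genes, a family chosen after the values were seen, 109 rose and 3 fell (median 0.68, 0.597 with median scaling and 0.462 with quantile normalization). In GREmx1-cre 32 of these rose and 0 fell (median 0.376), and in MREmx1-cre 16 rose and 1 fell (median 0.272). Negative control spots had a mean signal over local background of 10.2, 10.1 and 8.83 in GREmx1-cre, MREmx1-cre and GRMREmx1-cre, against 9.5 in dflox. Probes never well above background, a set that leaves out those raised on 3 arrays, had a median difference of 0.124 in GREmx1-cre, -0.163 in MREmx1-cre and -0.03 in GRMREmx1-cre, against 0.11, 0.144 and 0.274 for the dimmest part.

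**Figure D5:**
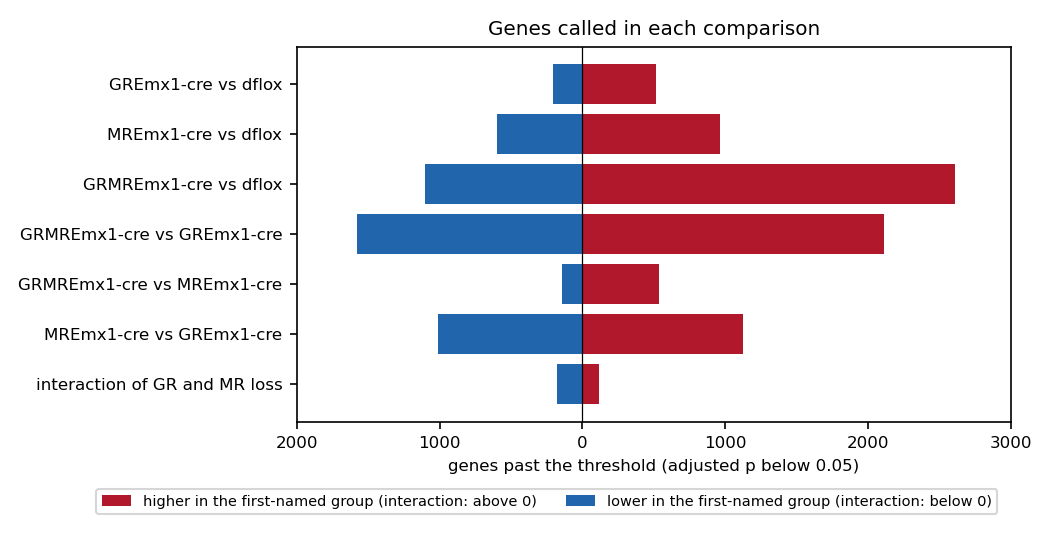
Number of genes past the adjusted threshold (horizontal axis) in each comparison (vertical axis), with bars to the right for genes higher and to the left for genes lower in the first-named group (for the interaction, above and below 0). The totals run from 295 genes for the interaction to 3716 for GRMREmx1-cre vs dflox.

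The comparison of GRMREmx1-cre with GREmx1-cre asks what further loss of MR adds where GR is absent. Aldh1a3 rose 12.4-fold (adjusted p = 7.69e-06, n = 3 and 4), Ocel1, a neighbour of Nr3c2, rose 5.61-fold and Cxcl5 rose 4.64-fold. C1qtnf3 (at least 2.88-fold, lost without GRMREmx1-cre replicate 2) and Olfr1044 (at least 1.13-fold) also rose. Spink8 fell 14.1-fold and Rasd1 7.96-fold (both adjusted p = 1.04e-05), with falls of Grem1 (at least 10.3-fold), the retrotransposon-derived Rtl3 (at least 2.71-fold) and Tmem215 (at least 2.14-fold). With normexp background correction these last 3 stood at 0.32, 1.003 and 1.18, and Nr3c2 at 0.63. In the model used here Nr3c1 was higher (0.60, adjusted p = 0.000646) and Nr3c2 lower (-0.73, adjusted p = 0.000383) than in GREmx1-cre. Dentate granule cell markers fell (mean -0.689, camera adjusted p = 2.27e-08; adjusted p = 0.144 with an estimated correlation; 12 fell, 2 rose). Microglia markers rose (mean 0.356, camera adjusted p = 4.85e-08; adjusted p = 0.138 with an estimated correlation; 11 rose, 0 fell). Adjusted over the list alone, 13 dentate markers fell and 2 rose, and 16 microglia markers rose. Lower as lists were also the corticosteroid-induced genes (mean -0.284, camera adjusted p = 0.000253; adjusted p = 0.229 with an estimated correlation), CA2 markers (-0.233, 0.000471; 0.0712), CA3 markers (-0.347, 0.00533; 0.138) and glutamatergic genes (-0.281, 9.18e-06; 0.144), where the numbers are the same quantities in the same order. Higher were the immature granule neuron markers (0.231, 0.0181; 0.138), activity-regulated genes (0.315, 0.0145; 0.543), reactive astrocyte genes (0.183, 0.0303; 0.543), activated microglia genes (0.377, 0.012; 0.473) and endothelial markers (0.181, 0.0237; 0.458). In total 3690 genes changed, 2110 up and 1580 down. The count was 2079 without GRMREmx1-cre replicate 2 and 2231 without GRMREmx1-cre replicate 3, and 68 of the 200 neighbours of Nr3c2 were among those changed.

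Against MREmx1-cre, joint loss shows what loss of GR adds where MR is absent. Etnppl fell 5.69-fold (-2.51, adjusted p = 0.00256, n = 3 and 4), Cyp4f15 fell 2.86-fold (adjusted p = 0.000432), Rasd1 fell 2.68-fold and Spink8 fell by 1.42 on the log2 scale (lost without GRMREmx1-cre replicate 2 or 3, -1.57 to -1.24). Nr3c1 fell as well (-2.18, adjusted p = 5.06e-08), and Nr3c2 stood at -0.19 (adjusted p = 0.31), with its probes differing in sign. Cxcl5 rose 7.56-fold (adjusted p = 0.00315), as did Gpr142 (8.22-fold), C1qtnf3 (at least 3.53-fold), Olfr979 (at least 2.76-fold) and Pdcl2 (at least 2.06-fold). Each of these last 4 calls was lost without at least 1 array, GRMREmx1-cre replicate 2 being such an array for each. Corticosteroid signalling components had a mean of -0.253 (camera adjusted p = 0.00291; adjusted p = 0.102 with an estimated correlation), with 2 fallers of 14 (3 adjusted over the list alone). The list holds Nr3c1, a faller by design, and without Nr3c1 and Nr3c2 its mean was -0.0975 (camera adjusted p = 0.0633), past no threshold. Also lower were corticosteroid-induced genes (mean -0.0883, camera adjusted p = 0.049), dentate granule cell markers (-0.18, 0.00456), glutamatergic genes (-0.102, 0.0184) and oligodendrocyte and myelin markers (-0.135, 0.0144). For the first of these the groups overlapped. The list mean relative to all arrays ran from -0.315 (replicate 1) to 0.0399 (replicate 3) in MREmx1-cre, and from -0.229 to -0.216 in GRMREmx1-cre. Activity-regulated genes (0.304, 0.00291), reactive astrocyte genes (0.132, 0.0312) and microglia markers (0.118, 0.00583) were higher, and for each of these 7 other lists the adjusted p was 0.683 with an estimated correlation. In total 681 genes changed, 538 up and 143 down. The count fell to 230 without GRMREmx1-cre replicate 2, 373 and 395 without GRMREmx1-cre replicate 3 and 1 and 412 without MREmx1-cre replicate 3. The share of rises of 79% fell to 62.88% with median scaling (288 up, 170 down).

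Between the single knockouts, MREmx1-cre had higher Aldh1a3 (8.18-fold), Nr3c1 (2.78, adjusted p = 9.18e-10), Ocel1 (5.56-fold), Etnppl (3.97-fold) and Hspb3 (3.87-fold) than GREmx1-cre (n = 4 and 4). It had lower Grem1 (7.1-fold), Olfml2b (5.61-fold), Tmprss6 (5.53-fold), Rtl3 (at least 2.98-fold), Tmem215 (at least 2.36-fold) and Nr3c2 (-0.54, adjusted p = 0.00203). CA2 pyramidal markers were lower (mean -0.387, camera adjusted p = 9.09e-06; adjusted p = 0.0146 with an estimated correlation; 8 of 16 fell), as were dentate granule cell markers (mean -0.509, camera adjusted p = 1.64e-06; adjusted p = 0.281 with an estimated correlation; 11 fell, 2 rose). Adjusted over the list alone, 10 CA2 markers fell and 2 rose, and 12 dentate markers fell and 2 rose. Corticosteroid-induced genes (mean -0.196, camera adjusted p = 0.0076), CA3 markers (-0.345, 0.000733) and glutamatergic genes (-0.179, 0.000733) were lower and microglia markers higher (0.238, 8.17e-06), with adjusted p = 0.457, 0.115, 0.333 and 0.237 with an estimated correlation. The choroid plexus markers were called lower (mean -1.04, camera adjusted p = 0.0438; adjusted p = 0.789 with an estimated correlation), a difference that rests on MREmx1-cre replicate 2. Relative to all arrays their mean was -4.14 on that array and 0.089 to 1.04 on the other MREmx1-cre arrays. In GREmx1-cre it ran from -0.199 to 0.986, so without that array the groups overlap. Here 2134 genes differed, 1124 higher and 1010 lower in MREmx1-cre, and median scaling moved the share of higher genes from 52.67% to 63.47% (1079 up, 621 down). Neighbours of Nr3c2 made up 64 of the genes that differed.

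The interaction asks whether joint loss departs from the sum of the single losses on the log2 scale. Crnde lay below that sum (-2.76 ± 0.305, adjusted p = 0.00259), as did the glycosyltransferase Ugt3a2 (-1.61, adjusted p = 0.0117), the transcription factor Tfap2b (-1.45, adjusted p = 0.00536), Rasd1 (-1.42, adjusted p = 0.0448) and the probe used for Nr3c2 (-0.62, adjusted p = 0.0394). The other Nr3c2 probes stood at -0.071 and -0.064. Nr3c1 stood at 0.06 (adjusted p = 0.832). Olfr401 was called below it, and the olfactory receptors Olfr1101 (2.04), Olfr73, Olfr218 and Olfr1044 and the cytokine Tnfsf12 above it. Where no value follows a name, the gene was above background on no array of at least 2 genotypes, so the size of its departure is not measured. Of these calls, those of Crnde, Ugt3a2 and Tfap2b held with each array left out, and each other one was lost without GRMREmx1-cre replicate 2, among other arrays. That of Rasd1 was lost without any 1 of 13 of the 15 arrays, and that of Nr3c2 without any 1 of 12. By the design as read here all GREmx1-cre mice lack the floxed Nr3c2 allele, a difference that leaving out single arrays cannot remove. Calls that held, Crnde among them, are therefore not shown to be free of it. With normexp background correction the values of Crnde (0.16), Ugt3a2 (0.72), Tfap2b (0.75) and Nr3c2 (0.67) turned above 0, and none of these passed the threshold. Activity-regulated genes lay above the sum (mean 0.676, camera adjusted p = 1.58e-09; adjusted p = 0.56 with an estimated correlation), with 1 of 22 members past the threshold, Fosb (1.16), and 11 adjusted over the list alone. Dentate granule cell markers (mean -0.287, camera adjusted p = 0.00699), glutamatergic genes (mean -0.155, 0.0277) and oligodendrocyte and myelin markers (mean -0.204, 0.0153) lay below it, and reactive astrocyte genes (mean 0.168, 0.0106) and fibroblast markers (mean 0.369, 0.00699) above it. With an estimated correlation the adjusted p was 0.631 for the oligodendrocyte list and 0.56 for the others. The fibroblast mean includes GREmx1-cre replicate 1, which was low for that list (-0.458 relative to all arrays, against 0.0335 to 0.115 on the other GREmx1-cre arrays). The glutamatergic call was lost without dflox replicate 3 (adjusted p = 0.116), GREmx1-cre replicate 1 (0.0922) or GRMREmx1-cre replicate 3 (0.0595). The reactive astrocyte call was lost without MREmx1-cre replicate 4 (0.0621) or GRMREmx1-cre replicate 2 (0.0627). The oligodendrocyte call was lost without dflox replicate 4 (0.0865), GREmx1-cre replicate 3 (0.0603), MREmx1-cre replicate 1 (0.0565) or GRMREmx1-cre replicate 2 (0.0627). The other 19 lists were not called (adjusted p from 0.072 to 0.987). In total 295 genes passed, 117 above and 178 below. Of the 200 neighbours of Nr3c2, 19 passed (9.5%, against 1.04% of the other genes with a symbol). The count was 83 and 104 without GRMREmx1-cre replicate 2 and 3. It was 125 and 145 without MREmx1-cre replicate 3 and 4, 143 and 166 without dflox replicate 3 and 1, and 149 and 151 without GREmx1-cre replicate 3 and 4.

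Calls in common were counted per direction. GREmx1-cre and MREmx1-cre shared 141 genes (123 up, 18 down, and 266 in all with slide position as a block), GREmx1-cre and GRMREmx1-cre 315 (268 up, 47 down), and MREmx1-cre and GRMREmx1-cre 1116 (658 up, 458 down). Independent lists of the same lengths would share 21.8 up and 5.28 down, 59.1 and 9.82, and 110 and 28.8. The comparisons share the dflox arrays, so chance overlap lies above these numbers, and a larger count alone does not show a shared effect of receptor loss. With the dflox arrays split between the comparisons, the shared calls numbered 10 to 22, 35 to 98, and 322 to 506. Each comparison then had 2 dflox arrays in place of 4, which lowers the number of calls by itself. The drop therefore does not measure the part due to shared controls. The fold changes correlated across genes, which are not independent replicates, at 0.403, 0.444 and 0.644, against 0.495, 0.462 and 0.458 for simulated unchanged groups with the same controls. Their covariances were 0.0364, 0.0554 and 0.0809 against 0.0283, 0.0286 and 0.0283. Etnppl fell in both lines that lack GR, and Dsp, Calb1, Spink8 and Fkbp5 fell and Aldh1a3 rose in both lines that lack MR. Etnppl also lay lower on every MREmx1-cre array (log2 level -1.32 to -0.52) than on every dflox array (-0.42 to 0.66). A lower level of it was therefore not particular to the lines that lack GR. The first shared count was 67 without dflox replicate 3, 71 and 91 without GREmx1-cre replicate 3 and 4, 81 and 89 without MREmx1-cre replicate 4 and 3, and 92 without dflox replicate 2. The shared count of GREmx1-cre and GRMREmx1-cre was 130, 191 and 204 without dflox replicate 3, 2 and 1 and 157 without GREmx1-cre replicate 3 or 4. That of MREmx1-cre and GRMREmx1-cre was 738 without dflox replicate 1.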

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

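The tests of dim probes, of granule cell markers and of GR loss acting near Nr3c2 were chosen after the result was seen, while the tests of other splits of the arrays and of variants beside the targeted loci were fixed beforehand, apart from a demand on the upper limit of the odds ratio that was added later.

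The real grouping of the arrays gave more changed genes than every other split of the same arrays that was run (1 of 35 splits, or 1 of 100 drawn for the interaction, gave as many). That 1 is the real grouping itself, so no smaller share could be reached, and the counts were not adjusted for each other. The other splits mix genotypes, which widens the spread within groups, so few calls were likely there beforehand. The splits therefore do not exclude chance. GREmx1-cre vs dflox gave 721 against at most 2 in another split, MREmx1-cre vs dflox 1557 against 1, GRMREmx1-cre vs dflox 3716 against 1014, GRMREmx1-cre vs GREmx1-cre 3690 against 56, GRMREmx1-cre vs MREmx1-cre 681 against 14, MREmx1-cre vs GREmx1-cre 2134 against 1, and the interaction 295 against 3. Each genotype lay on its own slide, so these splits say nothing about slide.

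Genes near Nr3c2 changed in GREmx1-cre vs dflox far more often than other genes (48 of 200, Fisher exact p = 5.06e-29, odds ratio 10.7 with 95% limits 7.43 and 15). GR acting on these genes would have moved them alike in GRMREmx1-cre, where GR was lost too, and 2 of the 48 were called in the same direction there, which argues against loss of GR acting on genes near Nr3c2. A strain variant linked to the floxed Nr3c2 allele, which GREmx1-cre alone lacks by the design as read here, may account for them, and it may act on the transcripts or on how well they bind the probes. It would carry over to the interaction, where 19 of 200 of these genes passed (Fisher exact p = 1.44e-12). Only 100 genes on either side were tested, so whether such a variant reaches other genes named for GREmx1-cre is not known. The same explanation found no counterpart beside Nr3c1 in MREmx1-cre vs dflox (9 of 200 genes, Fisher exact p = 0.106, upper limit of the odds ratio 1.11). Beside Emx1 Fisher exact p was 0.417, 0.137 and 0.449 in GREmx1-cre, MREmx1-cre and GRMREmx1-cre vs dflox. The ratios of shares (1.27, 1.39 and 1.12) lay under the 1.5 set beforehand, so the planned bound was met. Under the demand added later it stays open (upper limits of the odds ratio 2.61, 2.28 and 1.64). An odds ratio above 1 exceeds the ratio of shares, so the limit of 1.64 does not show that the ratio of shares in GRMREmx1-cre could pass 1.5.

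The dimmest of 5 equal parts of the genes was shifted up in GRMREmx1-cre vs dflox, with a median log2 difference of 0.274, and held 643 of the 2610 rises. The filter keeps probes raised on 3 arrays alone, and with probes filtered and ranked on the GREmx1-cre and MREmx1-cre arrays the difference was 0.193. A higher background on that slide would raise negative control spots, whose signal differed by -0.0236% of the 75th percentile (upper 95% limit 0.07, against a bound of 0.174 set from the lift of the dimmest part), which argues against it. Scaling each array to its median left that part at 0.192, which argues against the 75th percentile as the whole cause, in a test chosen after quantile normalization had been seen to give 0.0109. That method sets all arrays to 1 distribution, so a difference between slides that depends on intensity cannot be told apart from genotype here, and the loss of both receptors, a biological source, also stays open and was not tested.

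Dentate granule cell markers had lower means in both lines that lack MR, with list calls that were lost with an estimated correlation (adjusted p = 0.293 in MREmx1-cre and 0.15 in GRMREmx1-cre). A lower share of granule cells would lower all of them alike only if each were made in these cells alone. The markers did not move alike, since 7 of 19 tested markers in MREmx1-cre and 5 of 19 in GRMREmx1-cre had a 95% interval wholly above the median change of the list (4 and 6 wholly below). Whole hippocampus holds other cells that may make some of the markers, so this does not tell whether the share of granule cells was lower, which stays open. Changed expression within granule cells after loss of MR stays open and was not tested, and slide stays open as everywhere.

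The interaction of GR and MR loss passed for 295 genes. Lists past it had mean log2 values of -0.287 (dentate granule cell markers), -0.155 (glutamatergic genes), 0.676 (activity-regulated genes), 0.168 (reactive astrocyte genes), -0.204 (oligodendrocyte and myelin markers) and 0.369 (fibroblast markers), and with an estimated correlation none was called (adjusted p from 0.56 to 0.631). Genes named for it were Olfr73 (2.70), Olfr218 (2.33), Olfr1044 (2.31), Olfr1101 (2.04), Tnfsf12 (1.98), Crnde (-2.76), Olfr401 (-1.62), Ugt3a2 (-1.61), Tfap2b (-1.45), Rasd1 (-1.42) and Nr3c2 (-0.62, with its other probes at -0.071 and -0.064). Those of Olfr73, Olfr218, Olfr1044, Tnfsf12 and Olfr401 rest on signals below background in at least 2 genotypes, so they are not measured sizes.

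In 557 groups of 4 arrays, 38 had 1 array far from the other arrays of its group by Dixon's criterion, where chance marks about 1 in 20 groups. The group of 3 GRMREmx1-cre arrays was not tested. GREmx1-cre replicate 1 stood apart in its number of outlier spots (188 against 58 to 74), the SD of its negative controls (2.5 against 1.94 to 2.02), its median correlation with its group (0.983 against 0.991 to 0.992) and its place on the second principal component (-74 against -0.622 to 6.42). On that array the list mean was 0.323 for CA2 markers (0.0893 to 0.122 on the others), -0.458 for fibroblast markers (0.0335 to 0.115) and 0.435 for thalamus and habenula markers (-0.2 to -0.191), and the log2 level was -1.12 for Cyp4f15 and 1.37 for Ocel1. List means apart elsewhere were those of immature granule neuron markers on MREmx1-cre replicate 4 (-0.0331), of thalamus and habenula markers on MREmx1-cre replicate 1 (0.137) and of striatum and neocortex markers on dflox replicate 3 (0.119).

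Single genes of the naming rule past the threshold, or named outside it, had an array apart in 28 of 455 groups. Ttr (-2.58) and Kl (-2.44) were low on MREmx1-cre replicate 2 and Synpo2 (1.82) high on GREmx1-cre replicate 1, genes picked because of these arrays. On dflox replicate 3 the log2 levels were low for Fyb2 (-4.78), Grem1 (-4.32), Gria1 (5.86), Grik4 (3.64), Neurod2 (4.31) and Wipf3 (5.05). On dflox replicate 4 they were low for Il15 (-8.09), Mal (2.24) and Plekhf1 (-1.75) and high for Olfr979 (-6.67) and Sox11 (0.171). Low values were those of Gadd45b (0.742) and Gpr34 (-1.11) on dflox replicate 1, Arc (3.78) on GREmx1-cre replicate 4, Fibcd1 (1.29) on GREmx1-cre replicate 2 and Wfs1 (4.54) on MREmx1-cre replicate 1. High values were those of Hif3a (-2.12) on GREmx1-cre replicate 4, Pdk4 (-0.283) on MREmx1-cre replicate 1, Ocel1 (2.26) on dflox replicate 2, Amigo2 (-1.58) on GREmx1-cre replicate 4, Dera (-2.28) on MREmx1-cre replicate 1, Olfr1044 (-7.43) on MREmx1-cre replicate 2 and Klk1 (-5.04) on MREmx1-cre replicate 4.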

How the results depend on the processing

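The tests with arrays that stand apart left out, with normexp on each array's median background without genes near the targeted loci and without the targeted genes in the list of signalling components were chosen after the result was seen. The authors' value table, which holds the same intensities, changed nothing. Under planned normexp changed genes numbered 13 for GREmx1-cre vs dflox, 105 for MREmx1-cre vs dflox, 14111 for GRMREmx1-cre vs dflox, 14076 for GRMREmx1-cre vs GREmx1-cre, 13661 for GRMREmx1-cre vs MREmx1-cre, 173 for MREmx1-cre vs GREmx1-cre and 1 for the interaction, with 0, 3 and 101 shared calls (GREmx1-cre with MREmx1-cre, GREmx1-cre with GRMREmx1-cre, MREmx1-cre with GRMREmx1-cre) and 8 lists called in GREmx1-cre. On the GRMREmx1-cre arrays 9, 16 and 11 spots had a local background above their signal, and the fitted background means were -30.6, -804.5 and -107, against -0.331 to 2.42 on the others. Under it these values reversed sign: in GRMREmx1-cre vs dflox Grem1 0.49, Tmem215 1.33, Tmprss6 0.61, Nr3c2 0.96, Npnt 0.91, Amigo2 0.0044, S100b -0.0459 and Ptgs2 0.26, in GRMREmx1-cre vs GREmx1-cre Rtl3 1.003, Grem1 0.32, Tmem215 1.18 and Nr3c2 0.63, in the interaction Crnde 0.16, Olfr401 1.25, Ugt3a2 0.72, Tfap2b 0.75 and Nr3c2 0.67, and the test of activated microglia genes (mean 0.496). With normexp on the median background no sign reversed, so the reversals above rest on the planned fit of the GRMREmx1-cre arrays. With the median background 178 genes passed the interaction (134 of them as before), with 75 and 188 shared calls for the first and second pair.

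Counts for GREmx1-cre vs dflox were 425 with quantile normalization, 440 with median scaling, 471 with no filter, 346 with only the arrays compared, 414 with arrays apart left out and 236 with a fold minimum of 1.5. Median scaling gave 1029 for MREmx1-cre vs dflox and 182 for the interaction. Only the arrays compared, which is fewer arrays, gave 695 for MREmx1-cre vs dflox, 420 for GRMREmx1-cre vs MREmx1-cre and 1238 for MREmx1-cre vs GREmx1-cre. Array weights gave 1056 for GRMREmx1-cre vs MREmx1-cre and 793 for the interaction. Without the arrays apart the counts were 1104 for MREmx1-cre vs GREmx1-cre and 178 for the interaction, which with no filter was 138. With the fold minimum, which can only lower a count, they were 429, 1435, 1023, 313, 493 and 196 in the order above. Shared calls of the first pair were 71, 68, 75, 34, 93 and 26, and of the second 152, 175, 207, 135, 198 and 106, with quantile normalization, median scaling, no filter, only the arrays compared, arrays apart left out and the fold minimum, and those of the third were 520 and 323 with only the arrays compared and the fold minimum. Nr3c2 missed the threshold in GREmx1-cre under planned normexp (0.33) and without arrays apart (0.43), and in GRMREmx1-cre at -0.31 with no filter, only the arrays compared, eBayes trend and robust or arrays apart left out, and at -0.18 with normexp on the median background. With an estimated correlation 0, 3, 0 and 0 lists were called in GREmx1-cre, MREmx1-cre, GRMREmx1-cre and the interaction. Except where a mechanism is given, the cause was not tested.

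Leaving out each array gave 268 to 783, 1013 to 1591 and 2265 to 3897 genes for the 3 comparisons with dflox, 2079 to 3789, 230 to 757 and 1438 to 2139 between knockouts, 83 to 434 for the interaction and 67 to 150, 130 to 328 and 738 to 1144 shared calls. Lists called ran from 3 to 4, 9 to 10, 7 to 10 and 5 to 11 (11 without MREmx1-cre replicate 3, 10 without GRMREmx1-cre replicate 1). Nr3c1 ran from -2.29 to -2.19, 0.49 to 0.59 and -1.69 to -1.59, and Nr3c2 from 0.37 to 0.47, -0.17 to -0.06 and -0.36 to -0.21. The replicate numbers mark no shared animal, but each was also the array's position on its slide: with them as a replicate block the counts were 929, 1833, 3833, 3651, 801, 2412 and 307, with 266, 457 and 1252 shared calls, and Nr3c2 in GRMREmx1-cre stood at -0.29, past no threshold. Named results that missed it were also Chil3 and Klf1 in GREmx1-cre, Snap25 and Arc in MREmx1-cre, Col1a2 in GRMREmx1-cre, Olfr73, Rasd1 and Nr3c2 in the interaction, and the activated microglia list (adjusted p = 0.0711). After each gene's group mean was subtracted, same-numbered arrays of different groups correlated at -0.0259 to 0.194 (21 pairs, 6 of them over 0.1). On these deviations, 15 of 15 arrays had their highest mean correlation with arrays of their own number. The median CV of repeated spots was 5.91 to 6.3% at position 1, 3.91 to 4.58% at positions 2 and 3 and 5.35 to 5.43% at position 4, so position is an open explanation. Without genes near the targeted loci the counts with dflox were 665, 1513 and 3630. Of 238 named results, 221 kept their call with quantile normalization, 209 with median scaling and 188 of those tested with the filter on all 15 arrays, where 50 were not tested. Signal over background limits the rest.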
